A study of Solanum lycopersicum with 6 samples.

How the data were processed

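The deposited tables hold whole-number counts of unique molecular identifiers (UMIs) per gene and meristem, which the authors made by summing the wells of each meristem, per the series' design text. Per the labels' protocols, each shoot apical meristem was dissected, scored for its stage by shape, frozen and homogenized on its own, its RNA was captured on poly-dT beads, and it was placed in barcoded wells of MARS-seq plates, a 3′ method that counts molecules by UMI. Wells of a meristem are technical replicates, and the meristem was the replicate in the tests. The exceptions were the sums per dissection day and the reassignments of whole days, where the day was the unit. Reads were mapped with Bowtie2, per the submitters' processing notes; its version, the genome build and the annotation are not given in the sources used here. The deposited well-level counts were summed again for 658 meristems and were equal to the deposited profile for all 658; 33 loci of the wells are not in the tables. Stage, leaf number, plate and dissection day came from the deposited metadata, and the genotype from the labels. Of 28 batches of wells, 1 is listed under sft while its plate map gives wild type; the plate map was followed. Only wells and tables with a group in the labels were used.

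The tables hold 34102 lines, of which 1500 name more than 1 locus, so that overlapping genes and near-identical copies share counts there. Gene names and descriptions are those of the deposited tables; they cut descriptions to a few words, so word lists were matched to the shortened descriptions. In them the CLE9 locus is called CLE6, the FAB locus CLV1, the TKN2 locus STM, the MBP20 locus AP1 and the J locus J1. Of the 658 deep meristems 657 had a stage and entered a common fit. An extra uf stage, TM2E, was kept in the fit and in the day means over all stages, and in no contrast. Total UMIs per deep meristem and group are given with the results; 46 meristems lay under 237000 UMIs and were left out in an alternative.

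Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with min.count 5 on the groups of genotype and stage, trimmed mean of M values (TMM) factors, and the robust quasi-likelihood fit and test. This left 16306 genes with 99.9% of the UMIs. P-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05; "rose" and "fell" are used of called genes. SE of a log2 fold change is its size over the root of F. Contrasts needed 3 meristems per group. Mutants were compared with wild type at VM and, as the mean of the differences at each later stage with equal weight, after VM; interactions were contrasts of the same fit. A gene without UMIs in a group was set against the level of 3 UMIs over that group. Ratios of counts have 95% exact (Clopper-Pearson) intervals, and these and the floor cover counting error only. Leaf numbers were compared by two-sided permutation tests of the mean, exact with under 10 values in a group and with 100000 resamples otherwise, adjusted over the family. Expression was fitted on leaf number within VM for genotypes with at least 10 meristems. The shallow season was fitted alone.

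Gene lists were 5 by locus (floral meristem identity, floral organ identity, florigen family, meristem maintenance, boundary and axillary genes) and 13 by description (photosynthesis, ribosomal proteins, histones, cyclins, heat shock proteins, wound and defence, MADS-box, SBP-box, gibberellin, auxin, cytokinin, lipid transfer for the epidermis, vascular genes). Floral organ identity (3 members tested), the florigen family (4) and MADS-box (1) had fewer than 5 tested members and were not tested as lists. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one, with fry beside it, on log2 CPM with a prior count of 3. CPM of single genes were computed over totals scaled with the TMM factors. Named genes were SFT in every group, tested members of the 5 locus lists, and per comparison the 10 called genes with the largest rise and the 10 with the largest fall that had at least 20 CPM in the higher group. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

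The alternatives fixed beforehand were RLE factors, no filter, min.count 20, DESeq2 1.42.0, leaving out shallow meristems, thinning 591 meristems to 286929 UMIs each, plate or leaf number as a covariate, fits of the compared genotypes or the wild type alone, leaving out each meristem of groups of 3 to 5, medians of leaf number and estimated list correlations. Chosen after the data were seen were limma without and with the dissection day as a block (1 correlation, 0.188, from 2000 genes), edgeR on 1 sum per genotype and day, the day as a covariate of the leaf slopes, and fits without the 8 meristems that the metadata mark for low correlation or the shallow ones marked as mislabelled or diluted. The sums over the later stages pooled the counts of all these stages of a day, with no term for stage. The 20 days and the genotypes overlap little: wild type was dissected on 5 days, sft on 4, dst on 4, uf on 3 and sft dst on 6. Tables were read with the data.table package (1.17.8), wells with Python 3.11.15 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

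The tests were tried on simulated counts with 200 changed genes. They recovered 75% of 2-fold and 88% of 4-fold changes for wild-type EFM against VM (9469 genes), 55% and 90% for sft at VM (8525), 13% and 57% for uf at VM (10278), 6% and 44% for the interaction of sft and dst (13010), 78% and 94% for uf over the later stages (14755), 83% and 91% for the sft dst slope (7095) and 72% and 73% for the shallow season (4037). With a simulated spread between days over 12989 genes of sft against wild type, limma called 3713 genes without the block, of which 3514 were unchanged, and 302 with it, of which 140 were unchanged.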

Results

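The series holds transcriptomes of individually dissected tomato shoot apical meristems (cultivar M82-SP), the stem-cell-bearing shoot tip that makes leaves and then turns into a flower. Each apex was scored by its doming before RNA was taken. VM was a flat vegetative apex, TM0, TM1 and TM2 were transition apices at progressive doming, LTM was a late transition apex and EFM an early flower with floral organs. Wild type was represented by 209 meristems, with 23 at VM, 41 at TM0, 38 at TM1, 23 at TM2, 44 at LTM and 40 at EFM. The sft mutant, which lacks a working SINGLE FLOWER TRUSS (florigen) gene, was represented by 164 meristems, of which 1 had no stage. The dst mutant (delayed sympodial termination) was represented by 161 meristems, the uniflora mutant uf by 76, and plants carrying both sft and dst by 48, all at VM. A season of shallow libraries added 298 wild-type meristems. Median totals were 588748 unique molecular identifiers (UMIs) per wild-type meristem (100983 to 3804517), 883751.5 in sft, 597673 in dst, 901186 in sft dst, 747993 in uf and 97389 in the shallow season (10329 to 2166722). The 5 deep groups were dissected on 20 days. Values after ± are standard errors (SE) of a log2 fold change unless SD is named, n is the number of meristems, and CPM stands for UMIs scaled to 1e6 per meristem.

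SFT itself gave few UMIs, with a mean of 0.197 CPM in wild type, 0.949 in sft, 0.742 in dst, 0.0247 in sft dst and 0.0179 in uf. DST (Solyc03g006900) lay at 33.8 CPM in wild type, 36.8 in sft, 27.4 in dst, 36.3 in sft dst and 26.6 in uf. UF (Solyc09g005070) lay at 0.494 CPM in wild type, 0.222 in sft, 0.748 in dst and 0.141 in uf. No UF UMI was found in the 48 sft dst meristems, which allows up to 0.059 CPM over the group. The libraries counted 3′ tags, and a tag outside the lesion does not check a genotype.

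The first question was how many leaves each genotype had made when its apex was dissected at a given stage. A VM apex is still vegetative, so its leaf number also depends on when the plant was dissected. At VM, sft apices had 11.2 ± 0.866 leaves (SD, n = 12) and wild-type apices 7.65 ± 0.573 (SD, n = 23). At EFM the means were 12.1 ± 0.831 (SD, n = 21) and 7.52 ± 0.751 (SD, n = 40). At each of the 6 stages every sft meristem had more leaves than every wild-type meristem, with mean differences of 3.5 to 4.57 leaves. The dst apices had 10 ± 0.632 leaves at VM (SD, n = 6), 2.35 above wild type, with 5 of 6 above the highest wild-type value. From TM0 to EFM the dst differences were 3.83 to 4.42 leaves, and every dst meristem lay above every wild-type meristem. The sft dst apices were still vegetative at 20.1 ± 9.51 leaves (SD, n = 48), with a range of 7 to 46, and 42 of 48 lay above the wild-type maximum. The uf differences were smaller, at 0.9 leaves at TM0 (n = 5), 1.21 at TM1, 1.04 at TM2, 2.1 at LTM (n = 7) and 1.81 at EFM (n = 3). In two-sided permutation tests of the mean, the sft differences had adjusted p = 1.19e-05 at every stage, from p = 1e-05, the smallest that 100000 resamples can give. Exact permutation tests gave p = 4.21e-06 for dst at VM, and adjusted p = 0.0129 for uf at TM0, 1.64e-06 at LTM, 0.00235 at EFM and 0.086 at VM, where uf lay 0.6 leaves above wild type. With medians the uf calls at TM0 and TM2 ended (differences of 1 and 1, adjusted p = 0.179 and 0.81). Genotypes shared almost no dissection days. The permutation tests shuffled single meristems across days, so their p-values do not cover a spread between days. No test with the day as the unit was run on leaf numbers. Day means ran from 7 to 7.94 leaves in wild type, 11.5 to 12.1 in sft, 11.4 to 12.5 in dst, 8.77 to 10 in uf and 13.7 to 41.6 in sft dst.

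The next question was what changed in wild type between the vegetative apex and the early flower. A bark storage protein (Solyc08g066880) rose from 8 to 448 CPM (log2 fold change 5.82 ± 0.46, adjusted p = 2.54e-28), arginase 2, which breaks down arginine, from 6.49 to 191 CPM, and polyphenol oxidase from 18.8 to 355 CPM. A pair of leucine aminopeptidases rose by 5.84 ± 0.62 (Solyc12g010030) and 5.48 (Solyc12g010020), and LBD30, a LOB-domain regulator, by 4.83 ± 0.77. Among flower genes, TM5, a SEPALLATA3-type MADS-box gene, rose by 4.08 ± 0.47 (adjusted p = 3.3e-14), and FUL1, a FRUITFULL-type MADS-box gene, by 1.05 ± 0.25. J2, a SEPALLATA-type gene, had no UMI in 23 VM meristems and UMIs in 26 of 40 EFM meristems, at least 8.25-fold higher than the level of 3 UMIs over the VM group (adjusted p = 2.78e-07). On the same measure LIN was at least 3.81-fold higher (17 of 40 meristems) and SELF-PRUNING (SP), an antagonist of florigen, at least 4.44-fold higher (14 of 40). FALSIFLORA (FA), the tomato LEAFY gene, rose by 0.47 ± 0.15, WUS, which keeps stem cells, by 1.70 ± 0.53, and TKN1 by 0.97 ± 0.19. MC, whose counts share a line with the RIN locus, rose by 2.52 ± 0.41.

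Among the genes that fell from VM to EFM, a gibberellin receptor (Solyc07g040890) fell from 21.7 to 1.14 CPM (-4.15 ± 0.43). SSP, a bZIP partner of florigen, fell from 64.8 to 15.8 CPM (-2.04 ± 0.35, adjusted p = 1.13e-06), and TMF, which holds back the floral state, fell by 1.09 ± 0.20. CLV3, a stem-cell signal, fell by 1.85 ± 0.51 and BOP3 by 1.06 ± 0.26. In all 896 of 16306 genes were called in edgeR, of which 650 rose and 246 fell, and 574 differed by over 2-fold. With median-ratio (RLE) factors 564 rose and 335 fell. In DESeq2 the calls of J2, LIN, CLV3 and WUS ended (adjusted p = 0.104, 0.661, 0.0673 and 0.0996). Over all 6 stages 3103 genes differed.

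Of the gene lists, floral meristem identity had 5 of 13 tested members higher and 1 lower at EFM than at VM (6 and 1 adjusted over the list alone). Camera called it up (adjusted p = 0.0134), which it did not with an estimated correlation (adjusted p = 0.195 with an estimated correlation). Photosynthesis genes, a marker of leaf primordia on the apex, had 3 of 76 members higher and were called up (adjusted p = 0.0343, and adjusted p = 0.96 with an estimated correlation). The other 13 lists were not called, the smallest adjusted p being 0.855. Among these, members rose and fell as 6 and 2 of 370 ribosomal proteins, 6 and 3 of 60 auxin genes, 4 and 3 of 19 gibberellin genes, 2 and 4 of 27 lipid-transfer genes and 2 and 1 of 6 meristem maintenance genes. They did so as 2 and 0 of 25 wound and defence genes, 1 and 0 of 22 vascular genes, 1 and 0 of 15 SBP-box genes, 1 and 1 of 58 histones and 0 and 1 of 6 boundary genes. No member of the 26 cyclins, 42 heat shock proteins or 6 cytokinin genes passed the test.

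**Figure D1:**
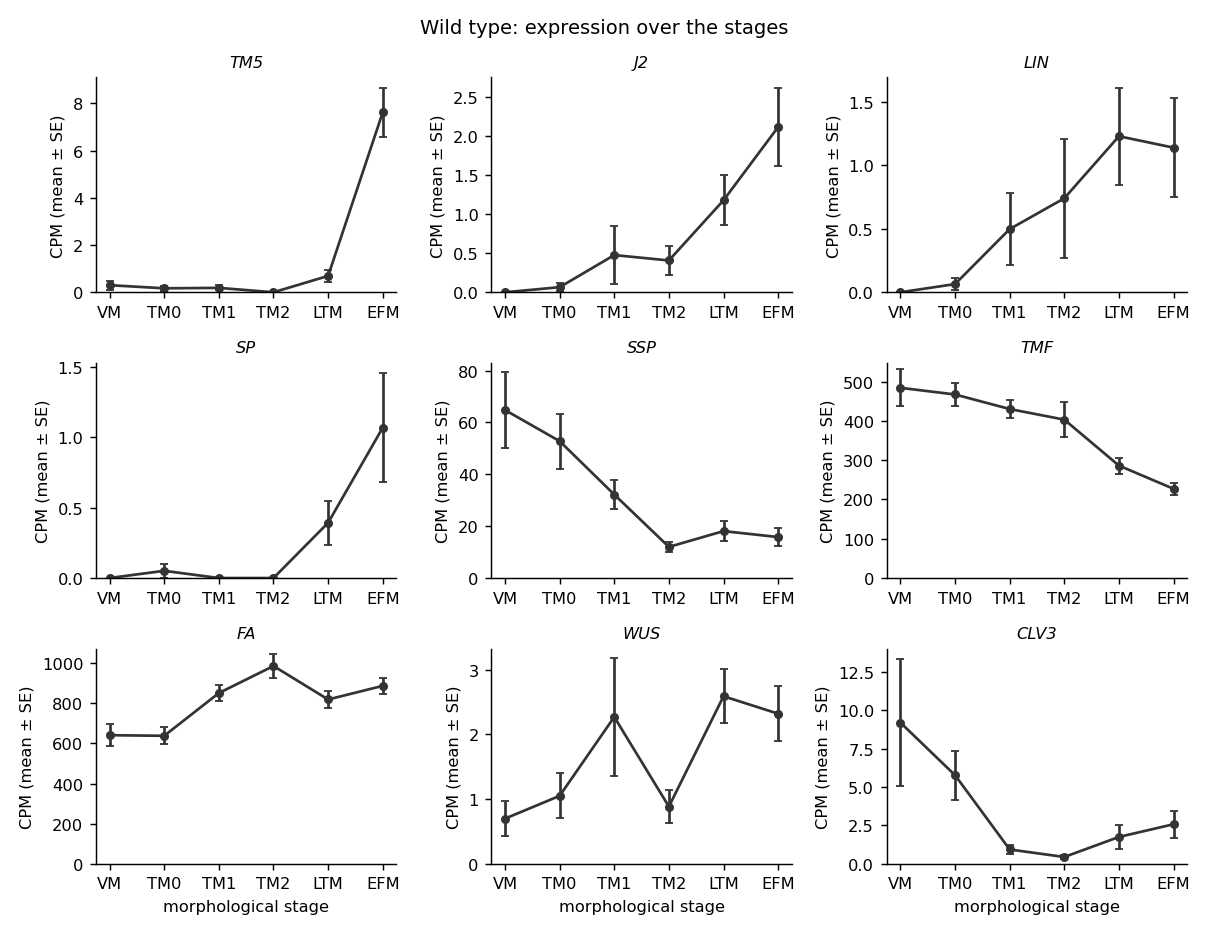
Mean CPM ± SE of TM5, J2, LIN, SP, SSP, TMF, FA, WUS and CLV3 at the 6 wild-type stages (23 to 44 meristems each). TM5 rose by 3.03 on the log2 scale from LTM to EFM, and SSP went from 64.8 CPM at VM to 15.8 at EFM.

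Step by step, the first doming stage differed least from the flat apex. Between VM and TM0 only chitinase (Solyc10g074440, -3.19 ± 0.59, 71.2 to 6.69 CPM, adjusted p = 0.00159) and a methanol-inducible gene (Solyc08g082120, -2.38 ± 0.52, adjusted p = 0.0369; named after its value was seen) fell in edgeR, and limma called 0 genes, with 579 genes at an unadjusted p under 0.05 in edgeR and 1 call in DESeq2. Between TM0 and TM1, 82 genes rose and 58 fell. PUCHI, an AP2/ERF gene of organ initiation, rose from 8.12 to 73.7 CPM (3.07 ± 0.47, adjusted p = 9.93e-07), LBD30 by 2.24 ± 0.46, an asparaginase (Solyc04g078460) from 35.8 to 126 CPM, FUL1 by 1.12 ± 0.21 and FUL2 by 1.14 ± 0.27. CLV3 fell by 2.63 ± 0.58, J1 by 1.35 ± 0.36 and CLV1 by 0.94 ± 0.26. Between TM1 and TM2, 159 genes rose and 24 fell, led by a leucine aminopeptidase (Solyc12g010020, 2.96 ± 0.42) and the bark storage protein (17.9 to 131 CPM, 2.87 ± 0.35, adjusted p = 2.19e-11). LBD30 rose again by 1.86 ± 0.46, while SSP fell by 1.40 ± 0.40.

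Between TM2 and LTM, 445 genes rose and 88 fell, the most calls of any step in this fit. That order did not hold in limma, which called 184 genes from TM1 to TM2 and 102 from TM2 to LTM (170 and 156 with the dissection day as a block), nor in edgeR fits of the 2 stages alone (103 and 66). TM5 had no UMI in 23 TM2 meristems and UMIs in 11 of 44 LTM meristems, at least 5.77-fold higher than 3 UMIs over the TM2 group, and SP was at least 2.72-fold higher (7 of 44). A ferredoxin (Solyc10g075160) rose by 3.37 ± 0.64 and asparagine synthase 1 by 2.25 ± 0.37. S, a WOX9-type gene of inflorescence branching, fell by 2.16 ± 0.45, PUCHI from 149 to 49.3 CPM (-1.60 ± 0.44) and BOP2 by 1.53 ± 0.37. Between LTM and EFM, 82 genes rose and 81 fell. TM5 rose by 3.03 ± 0.30 (adjusted p = 4.48e-18), an epidermal patterning factor (Solyc03g121790) from 16.4 to 53.4 CPM (1.67 ± 0.20) and SP by 1.29 ± 0.35. TAG1, an AGAMOUS-type gene, had 34 UMIs in 44 LTM meristems and 1 in 40 EFM meristems (adjusted p = 1.33e-06), a ratio of 33.1 with a 95% exact interval of 5.56 to 1350 that covers counting error only. That call ended in DESeq2 (adjusted p = 0.758), as did those of SP from LTM to EFM (0.962), TM5 from TM2 to LTM (0.366), PUCHI from TM2 to LTM (0.124) and LBD30 from TM1 to TM2 (0.172). With RLE factors the calls were 90 up and 97 down from TM0 to TM1, 122 and 44 from TM1 to TM2, and 739 and 67 from TM2 to LTM. RLE moved the median of all genes by -0.10 and 0.12 in the last pair of these steps. With the plate as a covariate edgeR called 1039 genes from TM2 to LTM.

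Along the steps, floral meristem identity genes were called up from TM0 to TM1 (adjusted p = 4.07e-06), with 2 of 13 higher and 1 lower (6 and 1 adjusted over the list alone), and this held with an estimated correlation (adjusted p = 0.00192 with an estimated correlation). Meristem maintenance genes were called up from TM2 to LTM (1 of 6 higher, 4 adjusted over the list alone), which also held (adjusted p = 0.0138 with an estimated correlation). No other step call held. Ribosomal proteins were called down from VM to TM0, up from TM0 to TM1 and from TM1 to TM2, and down from TM2 to LTM (adjusted p = 0.279, 0.204, 0.55 and 0.0743 with an estimated correlation). Histones were called up, up and down over the last 3 of these steps (adjusted p = 0.615, 0.55 and 0.379 with an estimated correlation). Heat shock proteins were called down from VM to TM0 and up from TM1 to TM2 (adjusted p = 0.279 and 0.271 with an estimated correlation). Boundary and floral meristem identity genes were called down from TM2 to LTM (adjusted p = 0.104 and 0.178 with an estimated correlation). The mean went against the call for ribosomal proteins from TM0 to TM1 (-0.01) and from TM2 to LTM (0.03), for histones from TM0 to TM1 (-0.04) and for floral genes from TM2 to LTM (0.02). From LTM to EFM no list was called (smallest adjusted p = 0.453).

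In the shallow wild-type season the flower (FM) differed from VM in several of the genes named above. LBD30 rose by 5.11 ± 0.69, a subtilisin by 5.6 ± 0.61, MC by 4.88 ± 0.62, the bark storage protein by 4.81 ± 0.71 and FUL1 by 1.53 ± 0.45. SSP fell by 2.47 ± 0.39, the gibberellin receptor by 3.23 ± 0.42 and TMF by 0.95 ± 0.19. FA rose by 0.53 ± 0.13 and TKN1 by 0.97 ± 0.24, and BOP3 fell by 1.05 ± 0.25. BOP2 fell by 1.16 ± 0.35 there and was not called between VM and EFM in the main season (-0.86 ± 0.38). STM, BOP1 and GOB were called in neither of these comparisons. TM5, J2, LIN, SP, WUS, CLV3 and the leucine aminopeptidases were not compared between the seasons. In all 492 of 5704 genes were called between 44 FM and 18 VM meristems, of which 188 rose and 304 fell, and 1562 differed over the 5 stages. With RLE factors 136 rose and 988 fell, and without shallow meristems 217 rose and 174 fell, so the direction of the majority depended on the setting. FM against VM here was set beside EFM against VM in the main season. Across 5683 genes tested in both seasons, which are not independent replicates, log2 fold changes had Pearson r = 0.626 and Spearman rho = 0.432. Of 389 genes called in the main season and tested here, 333 had the same sign (288 with RLE factors), as had 160 of 161 called in both.

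The sft apices at VM were low in FUL1. It fell from 29.4 to 0.716 CPM (-4.86 ± 0.53, adjusted p = 1.29e-14, 12 against 23 meristems), and a ferredoxin-NADP reductase (Solyc12g062200), an electron carrier enzyme of plastids, from 88 to 1.47 CPM (-5.74 ± 0.79). A glutaminase (Solyc03g006490) fell by 3.09 ± 0.53. Alcohol dehydrogenase (Solyc06g059740) rose from 5.5 to 90.7 CPM (4.02 ± 0.62) and a pyruvate decarboxylase (Solyc02g077240) by 2.48 ± 0.29 (adjusted p = 7.91e-13). Heat shock proteins had 6 of 42 members higher (7 adjusted over the list alone), among them Solyc08g062450 by 2.95 and Solyc06g036290 by 2.42. The list was called up by camera (adjusted p = 0.00539, and adjusted p = 0.56 with an estimated correlation), as were histones with 2 of 58 higher (12 adjusted over the list alone; adjusted p = 0.56 with an estimated correlation). In edgeR 467 genes were called, 227 up and 240 down, against 95 up and 504 down with RLE factors, which moved the median of all genes by -0.19. With the dissection day as a block, limma called 55 genes against 265 without it, and edgeR on sums per day called 0 (634 at an unadjusted p under 0.05). FUL1, the reductase, alcohol dehydrogenase, the decarboxylase and the glutaminase were still called with the block (adjusted p of 0.00195 at most), while these heat shock genes were called in limma neither with the block (adjusted p = 0.507 and 0.863) nor without it.

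Over TM0 to EFM the sft apices (151 against 186 meristems) were again low in FUL1, which went from 63 to 1.25 CPM (-5.42 ± 0.15, adjusted p = 2.35e-150). FUL2 fell from 45.6 to 12.8 CPM (-1.77 ± 0.14, adjusted p = 2.05e-29) and the reductase by 5.77 ± 0.24. A pair of SPL genes rose, with Solyc10g078700 going from 47.4 to 138 CPM (1.54 ± 0.08) and Solyc10g009080 rising by 1.45 ± 0.10, while the SBP-box list was not called (adjusted p = 0.054). A calreticulin (Solyc04g048900) rose by 3.36 ± 0.17, alcohol dehydrogenase from 13.2 to 109 CPM (3.35 ± 0.20) and TMF by 0.82 ± 0.09. Floral meristem identity genes were 1 of 13 higher and 6 lower, the same adjusted over the list alone, and were called down (adjusted p = 0.00051), also with an estimated correlation (adjusted p = 0.0297 with an estimated correlation). PUCHI fell by 1.61 ± 0.23, LBD30 by 1.59 ± 0.23, MC by 0.95, LIN by 0.93, TM3 by 0.70 and WUS by 1.03 ± 0.21, while SSP rose by 1.03 ± 0.15 and SFT by 1.34 ± 0.28. In edgeR 5857 genes were called, 2644 up and 3213 down, of which 376 differed by over 2-fold, against 1614 up and 4766 down with RLE factors (median of all genes moved by -0.10). Blocking on the day, limma called 189 genes against 5322 without it, and sums per day gave 81. Over the later stages the sums, here and for dst and uf, had no term for stage. The block kept FUL1, FUL2, both SPL genes, calreticulin, the reductase, alcohol dehydrogenase and TMF (adjusted p of 0.0202 at most), of which sums per day did not call alcohol dehydrogenase (0.0597) and TMF (0.197). In the simulation of this comparison with a spread between days, 140 of the 302 genes called with the block were unchanged. A call that the block kept, here or in the other comparisons of genotypes, can thus still come from days. The call of LIN had ended in limma without the block (-0.09, adjusted p = 0.0732). With the block the calls of PUCHI (-1.26 without and -1.38 with it, adjusted p = 0.0856), LBD30 (-1.10 and -1.16, 0.13), SSP (1.06 and 1.22, 0.0522), MC (-0.60 and -0.43, 0.52), TM3 (-0.21 and -0.22, 0.868), WUS (-0.21 and -0.14, 0.893) and SFT (0.20 and 0.13, 0.76) ended too.

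**Figure D2:**
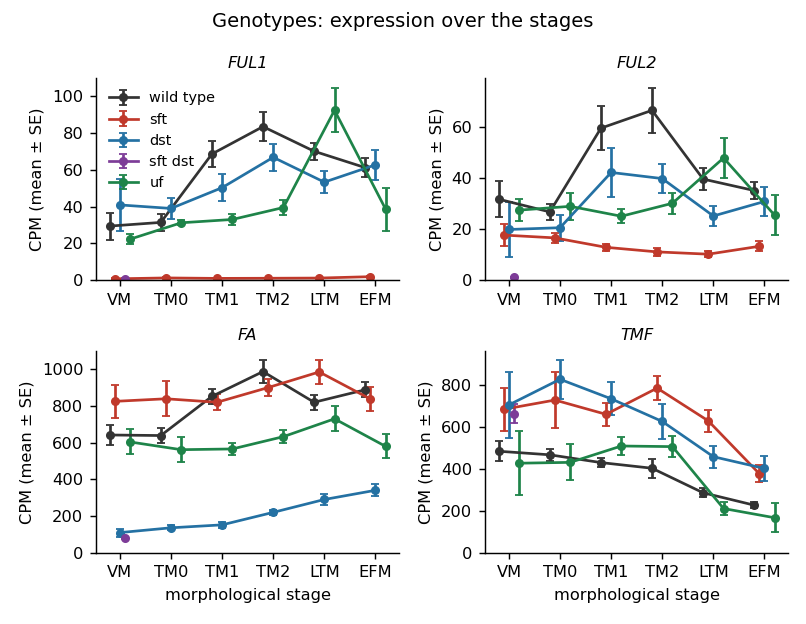
Mean CPM ± SE of FUL1, FUL2, FA and TMF by stage in wild type, sft, dst, uf and, at VM, sft dst. FUL1 averaged 1.25 CPM over the later stages in sft against 63 in wild type.

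The dst apices at VM (6 against 23 meristems) expressed a pair of genes of chromosome 4 that wild type did not. An SPL gene (Solyc04g081710) had 461 UMIs in 5 of 6 dst meristems and none in wild type, at least 449-fold higher than 3 UMIs over the wild-type group (adjusted p = 3.7e-14). An aldolase-family gene (Solyc04g081600) had 390 UMIs against 1, a ratio of 1140 (95% exact interval 204 to 45200). FA fell from 641 to 110 CPM (-2.54 ± 0.30, adjusted p = 2.16e-12), and the reductase had 1 UMI in dst against 1069 in wild type, a ratio of 366 (65.5 to 14500). SPL gene Solyc10g078700 rose by 1.54 ± 0.29 and a cyclin (Solyc04g081650) by 2.11. By locus number this cyclin lies between the chromosome 4 pair, and it is counted among their neighbours below. In edgeR 28 genes rose and 9 fell. Camera called floral meristem identity, ribosomal and photosynthesis genes down and heat shock proteins up (adjusted p = 0.394, 0.498, 0.498 and 0.498 with an estimated correlation). With the day as a block limma called 21 genes against 38, and it kept each gene named here (adjusted p of 0.0389 at most). Sums per day, in which the chromosome 4 SPL gene was not tested, called 2 genes, the aldolase-family gene and the reductase, with 295 genes at an unadjusted p under 0.05.

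Over the later stages the chromosome 4 pair stayed on in dst. The SPL gene had 8649 UMIs in 151 of 155 dst meristems and none in 186 wild-type meristems, at least 3420-fold higher than 3 UMIs over the group, and the aldolase-family gene 8350 UMIs and none, at least 3300-fold higher. FA fell from 836 to 228 CPM (-1.95 ± 0.06, adjusted p = 8.49e-123), the reductase by 4.90 ± 0.22 and a glutaminase (Solyc03g006490) changed by -2.29. SPL gene Solyc10g078700 rose by 1.85 ± 0.08 and a senescence-associated gene (Solyc04g072780) by 1.76. TMF rose by 0.74 ± 0.09, EJ2 by 0.99, J1 by 0.92, TKN1 by 0.76 and SFT by 1.12 ± 0.25, while FUL2 fell by 0.49 and TM3 by 0.63. Among fixed lists, histones had 30 of 58 higher and 12 lower, heat shock proteins 20 of 42 and 7, SBP-box genes 6 of 15 and 3, and photosynthesis genes 10 of 76 and 27. Camera called the first 3 up and the last down, and none held (adjusted p = 0.71, 0.606, 0.228 and 0.606 with an estimated correlation). In edgeR 8456 genes were called, 4342 up and 4114 down (155 against 186 meristems), of which 743 differed by over 2-fold. With RLE factors 3851 were up and 5155 down (median of all genes moved by -0.06), and in DESeq2 3497 and 5181. Under the block limma called 1288 genes against 8832, and sums per day called 7. The block kept the chromosome 4 pair, FA (7.26e-34), the reductase, the senescence-associated gene and Solyc10g078700. Of these, sums per day called the chromosome 4 pair and did not call FA (0.107), the reductase (0.494), the senescence-associated gene (0.554) or Solyc10g078700 (0.0599). With the block the calls of TMF (0.58 without and 0.58 with it, adjusted p = 0.0756), EJ2 (0.10 and 0.13, 0.204), J1 (0.37 and 0.57, 0.124), TKN1 (0.53 and 0.44, 0.0801), SFT (0.12 and 0.24, 0.087), FUL2 (-0.72 and -0.68, 0.126) and TM3 (-0.23 and -0.40, 0.215) ended.

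**Figure D3:**
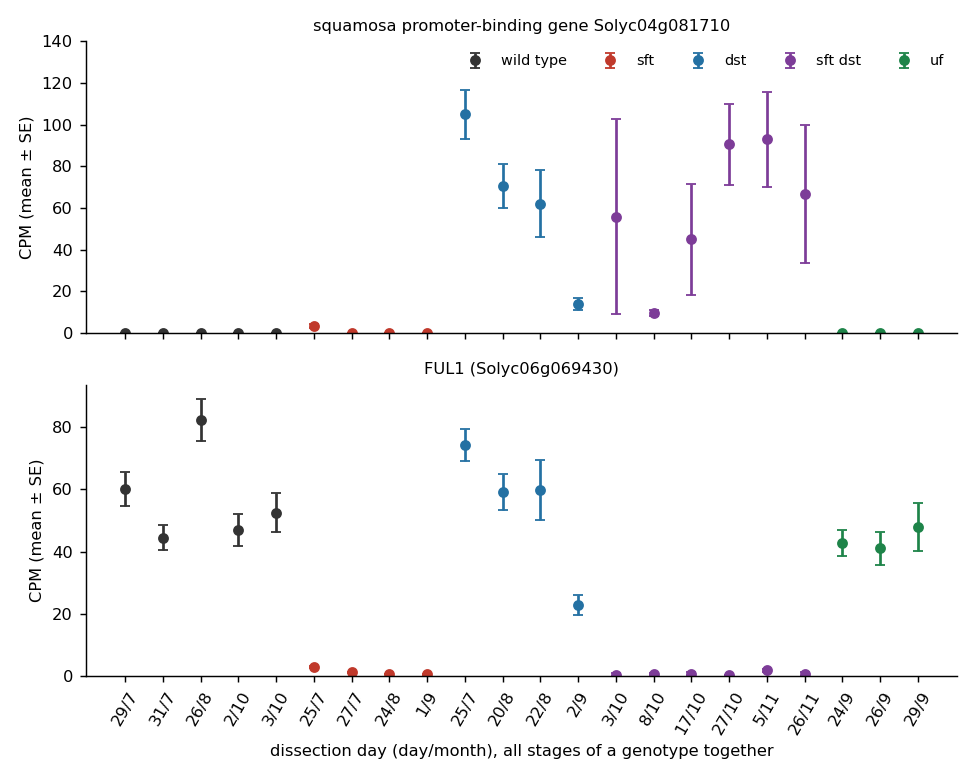
Mean CPM ± SE per dissection day of the chromosome 4 SPL gene (Solyc04g081710) and of FUL1 in each genotype. The lowest dst day mean of the chromosome 4 genes was 13.8 CPM, and the highest mean without dst on plates without dst was 0.0159 CPM.

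The vegetative apices carrying both mutations (48 against 23) were low in 9 of 13 tested floral meristem identity genes. FUL1 fell by 4.85 ± 0.30 (adjusted p = 2.72e-47), FUL2 by 4.60 ± 0.36 and FA from 641 to 82.8 CPM (-2.94 ± 0.14, adjusted p = 1.67e-75). MC, which marks sepals, had no UMI in 48 meristems against 32 UMIs in 11 of 23 wild-type meristems, at least 45.8-fold lower with 3 UMIs over the group as the floor. S fell by 2.30 ± 0.63, LS, which makes axillary meristems, by 1.91 ± 0.47, TM3 by 1.71, BL by 1.65 and SSP by 0.93, while TKN1 rose by 0.71. Adjusted over the list alone 1 rose and 9 fell, and the list was called down (adjusted p = 9.68e-14), also with an estimated correlation (adjusted p = 1.21e-07 with an estimated correlation). The chromosome 4 SPL gene had UMIs in 48 of 48 meristems, at least 362-fold higher than 3 UMIs over the wild-type group, and the aldolase-family gene went from 0.144 to 61.9 CPM. Another SPL gene (Solyc02g077920) rose by 2.09 ± 0.24. SBP-box genes were called up (4 of 15 higher, 1 lower; adjusted p = 0.0591 with an estimated correlation), though their median went from 0.13 to -0.04 with RLE factors. Photosynthesis genes (1 of 76 higher, 16 lower) and ribosomal proteins (11 of 370 higher, 40 lower) were called down (adjusted p = 0.125 and 0.499 with an estimated correlation). In edgeR 1894 genes were called, 1055 up and 839 down, against 585 up and 1215 down with RLE factors (median of all genes moved by -0.13). The count in limma was 2682 with the day as a block and 1841 without it, and sums per day called 61, of which 59 were among the 1894. The block kept FUL1, FUL2, FA, Solyc02g077920, TM3, SSP and TKN1, of which sums per day did not call TM3 (0.167), SSP (0.592) and TKN1 (0.485). The calls of S (adjusted p = 0.179), AP1 (0.226), EJ2 (0.563), LS (0.342) and BL (0.358) had ended in limma without the block, and that of MC ended with it (-0.61 without and -0.36 with it, 0.331).

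The departure from additivity of sft and dst at VM was tested as an interaction. FUL2 lay 3.22 ± 0.67 lower on the log2 scale in the combination than the sum of both mutants gave (-3.22, adjusted p = 0.000836), alcohol dehydrogenase fell short by 3.89 ± 0.94 (-3.89), and the reductase exceeded it by 14.55 ± 1.59, a fitted value that rests on 1 UMI in dst. Heat shock proteins had 9 of 42 members lower than additive, among them Solyc08g062450 (-7.51 ± 0.93), and histones 5 of 58. Both lists were called down (adjusted p = 0.246 and 0.618 with an estimated correlation). In edgeR 222 genes were called, 110 up and 112 down, against 174 and 155 with RLE factors and 386 and 181 in DESeq2. Blocking on the day, limma called 20 genes against 193 without it. Limma kept the reductase with the block, lost alcohol dehydrogenase with it (-2.75 without and -2.39 with it, adjusted p = 0.454), and called neither FUL2 (0.295 without and 0.905 with it) nor Solyc08g062450 (0.0627 and 0.582). RLE factors moved the median of all genes by 0.15.

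At VM the uf apices (4 against 23) differed in 5 genes, 3 up and 2 down. An ethylene-responsive factor (Solyc06g009810, 4.9 ± 0.5, adjusted p = 2.5e-14; named after its value was seen), cathepsin D (Solyc03g098780, 4.45 ± 0.78) and a BED zinc finger gene (Solyc11g040105, 3.25 ± 0.74) were higher, and an RNA-binding protein (Solyc09g090520, -2.28 ± 0.50) and a CONSTANS-interacting protein (Solyc01g079870, -1.92 ± 0.42) lower. Heat shock proteins were called down (adjusted p = 0.695 with an estimated correlation). Under the day block limma called 2 genes, and of these 5 only the ethylene-responsive factor (6.63e-18); the calls of cathepsin D and the BED zinc finger gene had ended in limma without the block (0.396 and 0.138). The cathepsin D value rested on 1 meristem, without which it was 1.73 (adjusted p = 1). With each uf meristem left out in turn, the call of the RNA-binding protein ended in 4 of 4 fits (adjusted p of 0.0659 to 0.251), and those of the BED zinc finger gene (0.164 to 0.525) and the CONSTANS-interacting protein (0.127 to 0.523) in 3 of 4.

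Over TM0 to EFM, uf apices (54 against 186) were low in LBD30, PUCHI and S. LBD30 fell by 4.54 ± 0.64, PUCHI by 3.73 ± 0.60, S by 3.18 ± 0.52 (adjusted p = 1.91e-07), WUS by 1.62 ± 0.36, LIN by 1.47, FUL1 by 0.49 and FA by 0.44 ± 0.11. SSP rose from 26.2 to 101 CPM (1.84 ± 0.22, adjusted p = 3.49e-13), CLV3 by 1.95 ± 0.41 and CLE6 by 2.08 ± 0.36. EJ2 had no UMI in 54 uf meristems against 32 in wild type, at least 3.26-fold lower with 3 UMIs over the group as the floor, and SFT had 1 UMI against 37, a ratio of 11.3 (95% exact interval 1.91 to 458). The BED zinc finger gene was 2.96 ± 0.25 higher and the RNA-binding protein 2.04 ± 0.19 lower (-2.04). Heat shock proteins had 2 of 42 higher and 18 lower, ribosomal proteins 50 of 370 and 106, and histones 3 of 58 and 13. All 3 lists were called down and none held (adjusted p = 0.291, 0.821 and 0.865 with an estimated correlation). With RLE factors the ribosomal and histone medians went from -0.12 and -0.17 to 0.08 and 0.02. Floral meristem identity genes, with 0 of 13 higher and 5 lower, were not called (adjusted p = 0.176). In edgeR 5129 genes were called, 2583 up and 2546 down, of which 1091 differed by over 2-fold, against 4058 up and 1240 down with RLE factors (median of all genes moved by 0.17). With the day as a block limma called 28 genes against 5392, and sums per day called 5, namely S (0.00985), the ethylene-responsive factor (0.000615), a late embryogenesis gene, a lipid-binding gene and a glycine-rich gene. With 7 uf meristems at LTM and 3 at EFM, against 44 and 40 in wild type, these sums mix genotype with stage. The block kept the BED zinc finger gene (1.44e-05) and the RNA-binding protein (1.26e-07), while the calls of LBD30 (-1.58 without and -1.59 with it, adjusted p = 0.361), PUCHI (-1.68 and -1.65, 0.547), SSP (1.63 and 1.41, 0.393), S (-1.12 and -1.17, 0.595), WUS (-0.24 and -0.25, 0.998), CLV3 (0.59 and 0.38, 0.998), CLE6 (0.64 and 0.49, 0.998) and FA (-0.40 and -0.31, 0.998) ended with it. Those of LIN (0.0954), FUL1 (0.113), EJ2 (0.212) and SFT (0.529) had ended in limma without the block. Without uf EFM replicate 3 the count was 2912 and the CLV3 call ended (1.56, adjusted p = 0.177), and the FUL1 call ended without EFM replicate 1 (0.0782) or 3 (0.0826).

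Whether a mutant changed the transition itself was tested as the difference between its later stages and VM against the same difference in wild type. For sft a pair of heat shock genes was called, Solyc08g062340 (-4.78 ± 0.72, adjusted p = 1.11e-06; 4.81 at VM and 0.03 later) and Solyc03g123540 (-2.49 ± 0.52, adjusted p = 0.0151; 2.13 at VM and -0.36 later), both named after their values were seen. Photosynthesis genes were called up and histones and heat shock proteins down (adjusted p = 0.321, 0.321 and 0.325 with an estimated correlation). For dst edgeR called 0 genes (555 at an unadjusted p under 0.05, smallest adjusted p = 0.788), DESeq2 1 and limma 2. For uf edgeR called 0 genes (287, smallest adjusted p = 0.231), DESeq2 2 and limma 0. Ribosomal and boundary genes were called up for dst (adjusted p = 0.474 and 0.401 with an estimated correlation), and ribosomal proteins and histones down for uf (adjusted p = 0.803 and 0.846 with an estimated correlation). With the day as a block limma called 7 genes for sft, against 3 without it, and neither heat shock gene was among the 7 (Solyc03g123540 -1.01, adjusted p = 0.622, and -0.94, adjusted p = 1 without the block; Solyc08g062340 -0.53, 0.238, and -0.52, 0.543). With the plate as a covariate edgeR called 0 genes (2 without it).

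Both mutants were compared for shared effects at VM, where sft and dst were set against the same wild-type meristems. Genes called up in both included the pyruvate decarboxylase, SPL gene Solyc10g078700 (0.95 in sft and 1.54 in dst) and the senescence-associated gene (1.27 and 1.68). Of the 13 genes called in both with the same sign, limma called 6 in both without the day block and 3 with it, the senescence-associated gene, the reductase and a retrovirus-related gene (Solyc01g010190). The decarboxylase was not called in dst in limma without or with the block (0.98, adjusted p = 0.324, and 0.96, 0.507), its dst value held 1 meristem apart from the rest, and its dst day means (8.82 to 66.4 CPM) overlapped those of wild type (6.02 to 15.9). Limma did not call Solyc10g078700 in sft at VM without the block (0.80, adjusted p = 0.0625) or with it (0.83, 0.143). In all 12 genes rose in both, 0.39 being the number for independent lists, 1 fell in both, the reductase (0.132 for independent lists), and 0 went opposite ways. The counts fell to 3 up in both and 1 down in a fit of these 3 groups alone, and to 0.15 and 1.05 on average with separate wild-type meristems for each mutant. With these smaller wild-type groups dst had only 3.3 genes up and 5.9 down on average. The numbers for independent lists were then 0.00584 up and 0.0207 down. Across genes, which are not independent replicates, log2 fold changes had r = 0.396 and covariance 0.181 in the planned fit, and r = 0.506 and covariance 0.123 in the fit of the 3 groups. Unchanged simulated groups against the same wild-type meristems, fitted as these 3 groups were, gave a covariance of 0.00976 and a mean r of 0.074 (highest 0.095), without any simulated difference between days. Since sft and dst shared a dissection day with each other and none with wild type, the simulated value does not cover a change that days brought to both. With separate wild-type meristems r was 0.231 on average and -0.018 at the lowest. The covariance was then 0.0642 on average and -0.0064 at the lowest, against 0.123 with shared ones. This fall was larger than the simulated 0.00976, so the simulation understated the part that shared wild-type meristems bring.

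Within VM, expression was set against leaf number, the recorded age of an apex. In sft dst 79 genes rose and 73 fell with leaf number (152 of 7095). STM, a stem-cell homeobox gene, rose by 0.033 ± 0.006 log2 units per leaf (adjusted p = 0.000842), an auxin-repressed dormancy gene (Solyc02g077880) by 0.05 ± 0.011 and a lysine ketoglutarate reductase by 0.049 (adjusted p = 6.49e-05), while a histone H4 fell by 0.041 ± 0.01. FA had a slope of -0.022 ± 0.008 (adjusted p = 0.125). Leaf number was partly confounded with the dissection day, with day means of 13.7 to 41.6 leaves. With the day as a covariate 2669 genes were called, among them 126 of the 152, and the slopes were 0.043 ± 0.01 for STM, 0.119 ± 0.013 for the dormancy gene, 0.067 ± 0.014 for the reductase of lysine and -0.09 ± 0.015 for the histone (adjusted p of 0.0018 at most). Auxin genes were called up (2 of 24 higher, 4 adjusted over the list alone), also with an estimated correlation (adjusted p = 0.0198 with an estimated correlation), and ribosomal proteins and histones down (adjusted p = 0.398 and 0.43 with an estimated correlation). The lists were not tested with the day as a covariate. Without the lowest and highest leaf numbers 77 genes were called. In wild type edgeR called 0 of 4750 genes (205 at an unadjusted p under 0.05) and in sft 0 of 4837 (52), and no other tool was run on the slopes. Ribosomal, histone and heat shock lists were called up with leaf number in wild type and photosynthesis genes down in wild type and sft, and none held (adjusted p = 0.22, 0.361, 0.285, 0.361 and 0.693 with an estimated correlation).

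Dissection days within a genotype mostly differed as widely as genotypes did. Between wild-type meristems of October and July, over the later stages, 7216 of 12568 genes were called in edgeR (68 against 79 meristems), and at VM 609 (10 against 10). Those of August and July differed less, in 3675 of 12798 genes over the later stages (39 against 79). The later sft meristems of August and September differed from those of July in 9301 genes (84 against 67), and those of dst in 8341 (105 against 50). On the single day shared by wild type and sft dst, 312 genes were called at VM (7 against 4 meristems), 247 up and 65 down. These sft dst apices had a mean of 16.9 leaves, and the wild-type apices of that day, over all stages, 7.84. Leaf number was therefore not told apart from genotype there. On plates that held both sft and dst, 410 genes differed between them (15 against 37).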

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

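The tests of depth, of the chromosome 4 stretch, of carried-over RNA and of the reductase were chosen only after their results were seen; the reassignments of days and the splits of meristems were set beforehand.

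Among 29 sets of values in groups of 4 to 10 meristems, 12 held a meristem far from the rest by Dixon's gap test, which flags about 1 in 20 groups of normal values by chance. These were raw CPM, totals and whole leaf numbers, and many were of genes named because they were called in the same meristems. Whole numbers that tie but for 1 value are flagged by construction. The number of flags is therefore not read as an excess. In the 6 dst meristems at VM the highest value stood apart for a cyclin (Solyc04g081650, 63.4 CPM, next 25.4), a Dof zinc finger gene (151, next 34), a ganglioside-induced gene (Solyc02g083250, 140, next 62), pyruvate decarboxylase (145, next 37) and SPL gene Solyc10g009080 (490, next 119). It also did for a transcription factor (Solyc01g104650, 136, next 60.5), the ferredoxin-NADP reductase (2.88, next 0) and FA (213, next 107). Among uf meristems at TM0 the highest total was 2680000 UMIs (next 778000) and the lowest leaf number 8 (next 9). Among the 4 uf meristems at VM the highest leaf number was 9 (next 8) and the highest cathepsin D value 107 CPM (next 9.71).

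In an interaction test of sft and dst at VM edgeR called 222 genes, and limma with the day as a block called 20, of which 18 were among them. The larger log2 differences in edgeR were 14.55 for the reductase, 7.94 for Solyc04g071890, 3.07 for a pentatricopeptide repeat gene (Solyc06g074400), 2.61 for a tonoplast protein (Solyc06g074820), 2.4 for a receptor-like kinase (Solyc03g083510), 2.35 for a ribonuclease H2 gene (Solyc02g069070) and 2.33 for a DNA-directed RNA polymerase gene (Solyc12g013530). Further ones were 2.3 for a KH RNA-binding gene (Solyc06g082620), 2.21 for a ZF-HD homeobox gene (Solyc02g067310) and 2.2 for a transmembrane gene (Solyc03g117055). On the negative side stood -8.94 for Solyc07g052700, -5.44 for Solyc07g052707, -3.89 for alcohol dehydrogenase, -3.65 for a class 2 gene (Solyc03g007890), -3.32 for Solyc09g008970 and -3.22 for FUL2. Heat shock genes gave -7.51 (Solyc08g062450), -5.48 (Solyc06g036290), -5.12 (Solyc08g078695), -3.58 (Solyc03g123540) and -3.49 (Solyc06g076020). Of these 21 genes, the block kept the reductase, Solyc04g071890, the pentatricopeptide repeat and tonoplast genes, Solyc07g052700 and Solyc07g052707 (adjusted p of 0.001 at most). The calls of the ribonuclease H2 (0.427), RNA polymerase (0.123), KH (0.265), ZF-HD (0.24) and transmembrane genes (0.135) and of alcohol dehydrogenase (0.454) ended with the block. The receptor-like kinase (0.0883), the class 2 gene (0.468), Solyc09g008970 (0.348), FUL2 (0.295) and the 5 heat shock genes (0.0627 to 0.545) were not called in limma even without it. For sft and stage edgeR called 2 heat shock genes, with values of -2.49 (Solyc03g123540) and -4.78 (Solyc08g062340). In the fit of the compared meristems alone the count was 1, and chance could not be excluded (58 of 100 splits as large). Limma called neither gene without the block (adjusted p = 1 and 0.543) or with it (0.622 and 0.238), and with the plate as a covariate edgeR called 0. In data outside the comparisons, 55 sets of wells belonged to meristems that are in none of the tables used, with a median of 234 gene UMIs per spike-in UMI, against 9.52 in 49 sets of wells without a meristem and 1740 in those used. These 55 sets held 3737 to 99307 gene UMIs, and those used at least 101240. All meristems left out of the tables thus had fewer UMIs than any meristem in them.

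Many small differences set each mutant apart from wild type over the later stages. Thinning the 591 deeper meristems to an equal total, without the rest, left 2785 genes called for sft, 5130 for dst and 1840 for uf, which argues against unequal depth as the whole cause. When whole dissection days were reassigned between the genotypes, 48 of 100 reassignments called as many genes as the real one for sft (5253 genes, highest other 9722), 40 of 100 for dst (highest other 9557) and 14 of 56 for uf (7101 and 9973), so chance could not be excluded; with the day as a block limma called 189, 1288 and 28 genes. At VM this was so for 25 of 100 in sft (70 and 3656), 18 of 56 in dst (11 and 1922) and 21 of 100 in sft dst (1438 and 6558), where the block left 55, 21 and 2682 genes, and counts several times the real one point to a structure of the samples by day. A difference between days may account for many of these genes, and genotype stays open, since sft, dst and uf share no day with wild type and sft dst shares 1.

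A pair of chromosome 4 genes, the SPL gene Solyc04g081710 and the aldolase-family gene Solyc04g081600, had UMIs in 156 and 159 of 161 dst and in 48 of 48 sft dst meristems, against 0 and 1 of 209 in wild type. RNA carried over from other samples is argued against as their source, since the highest mean without dst on plates without dst was 0.0159 CPM and the lowest dst day mean 13.8 CPM. Of 24 tested neighbours 4 differed over 2-fold the same way in dst and sft dst. Among them was the cyclin Solyc04g081650 (1.62 in dst over the later stages and 1.79 in sft dst at VM). Of 15929 stretches of as many genes, 0.213% held as many. A stretch of another haplotype around the pair in the dst line is therefore a candidate explanation. The stretches overlapped each other and included those around the pair, so the share does not come from independent stretches elsewhere. On 2 plates shared with dst, sft meristems had traces of both genes (6 of 6 and 8 of 10 meristems for the SPL gene, at 3.65% and 2.27% of the dst mean), and on other plates 0 of 147 and 1 of 147 had any (larger Fisher's exact p = 4.76e-14), which fits RNA carried over within a plate. However, sft and dst also shared a dissection day, with 16 sft meristems. Carry-over at dissection was not told apart from carry-over on the plate. Whether the dst mutation itself turns on the pair was not tested.

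The ferredoxin-NADP reductase (Solyc12g062200) was low in sft and dst and high in sft dst. Unequal depth is argued against, since its log2 fold change in sft was -5.11 after thinning and stayed called. Day means lay apart from those of wild type in sft at VM (0 to 5.56 against 12.6 to 119 CPM) and over the later stages (1.28 to 1.97 against 3.21 to 149) and in dst at VM (0 to 1.44), and overlapped only in dst over the later stages (0.207 to 13). Over all stages wild-type day means themselves ran from 3.89 to 145 CPM, so a difference between days may account for part of the pattern. Genotype stays open as well.

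Splits of the same meristems into groups of the real sizes, 100 per comparison with the real one included, were fitted on the compared meristems alone. They shuffle single meristems across days, so for genotypes they do not test a difference between days, for which the reassignments of whole days above did not exclude chance. Nor do they for the leaf slope in sft dst, where leaf number and day are partly confounded. Among shuffled single meristems, 1 to 3 of 100 splits were as large in the comparisons listed next. This makes chance less likely and does not exclude it, since the numbers were not adjusted over the comparisons. It held for wild-type TM0 to TM1 (2 splits as large, 37 genes, highest other 307), TM1 to TM2 (3, 103 and 510), TM2 to LTM (1, 66 and 20), LTM to EFM (3, 59 and 442), EFM against VM (1, 651 and 245) and any stage (1, 2136 and 631). The same held for sft at VM (3, 167 and 2731), dst at VM (3, 12 and 30), sft dst at VM (2, 1236 and 2083), their interaction (2, 193 and 370), the later stages of sft (1, 5578 and 2172), dst (1, 7250 and 972) and uf (1, 5660 and 820), the sft dst slope (2, 152 and 506) and the shallow season (1, 1562 and 237 over its stages, and 1, 492 and 320 for FM against VM). Chance could not be excluded for the sft and uf interactions with stage (58, 1 and 2090; 50, 1 and 1902). The real count was 0 for VM to TM0 (100, highest other 2), uf at VM (100, 431), the dst interaction with stage (100, 887) and the slopes of wild type and sft (100, 399; 100, 653), so that each split was as large by construction and nothing was tested. Splits that called several times the real count, up to 2731 genes for sft at VM, point to a structure of the samples.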

How the results depend on the processing

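The fits of limma with and without the day as a block, the sums per day, the day as a covariate and the fits without meristems that the authors mark were chosen only after the data were seen. Of 330 named gene results, the call and direction were the same in 317 with RLE factors, 312 without a filter, 307 without shallow meristems, 214 of 317 after thinning, 295 of 324 in DESeq2, 111 of 125 with the plate as a covariate, 251 in limma and 183 in limma with the day as a block; they were 297 of 298 with min.count 20, 107 of 112 in the wild type alone, 318 without meristems the authors left out, 187 of 206 with leaf number as a covariate, 183 of 191 in a fit of the genotypes compared, 30 of 172 in sums per day and 276 of 296 with 1 meristem left out. In the rest the call ended, except that chitinase (Solyc10g074440) in sft dst turned to 0.06 with the day as a block (adjusted p = 0.946). The cause of the differences below was not tested. Thinning, however, removes counts from every meristem above the set total and leaves out those below it.

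Counts of called genes that moved by over 1.5 times follow. From VM to TM0 (2 reported) RLE, min.count 20, DESeq2 and the wild type alone gave 1, while leaving out shallow meristems, thinning, the plate covariate and limma with or without the block gave 0. Thinning gave 33 from TM0 to TM1, 65 from TM1 to TM2, 95 from TM2 to LTM, 34 from LTM to EFM, 283 for EFM against VM and 1235 for any stage. For TM2 to LTM (533) RLE gave 806, min.count 20 gave 280, the plate covariate 1039, the wild type alone 174, limma 102 and its block 156. For LTM to EFM (163) min.count 20 gave 63, DESeq2 100, the wild type alone 74 and limma 104, and for any stage (3103) min.count 20 gave 2037.

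For sft at VM (467) no filter gave 268, DESeq2 965, leaving out shallow meristems 780, thinning 79, a fit of both genotypes alone 723, limma 265, its block 55 and sums per day 0 (634 at an unadjusted p under 0.05). For dst at VM (37) thinning gave 16, the block 21 and sums 2. For sft dst (1894) thinning gave 462, leaf number as a covariate 1249 and sums 61. For uf at VM (5) RLE, no filter and leaving out meristems the authors left out gave 8, DESeq2 15, and leaving out shallow meristems, thinning, the fit of both genotypes and the block 2. Over the later stages thinning, the block and sums gave 2785, 189 and 81 for sft, 5130, 1288 and 7 for dst and 1840, 28 and 5 for uf. The interaction of sft and dst (222) gave 567 in DESeq2, 131 thinned and 20 with the block. For sft and stage (2) min.count 20 and the own fit gave 1, DESeq2 5, leaving out shallow meristems 9, the plate covariate 0, thinning 3 and the block 7. For dst and stage (0) DESeq2 gave 1, limma 2 and its block 1, and for uf and stage (0) no filter 1, DESeq2 2 and the own fit 1.

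The sft dst slope (152) gave 77 without the lowest and highest leaf numbers, 1292 with the plate and 2669 with the day as a covariate; for the wild type, dropping the extreme leaf numbers left a single leaf number, and no slope could be fitted. In the shallow season min.count 20 gave 664 over all stages, and FM against VM (492) gave 1124 with RLE and 249 with min.count 20. Without shallow meristems 217 rose and 174 fell, against 188 and 304. With medians the uf leaf differences at TM0 and TM2 were 1 and 1 and no longer called. With an estimated correlation camera called 1 list for TM0 to TM1, TM2 to LTM and sft dst, and 0 for VM to TM0, TM1 to TM2, EFM against VM, for sft, dst and uf at VM, for the later stages of dst and uf and for the interactions; of 43 list calls 4 held. Leaving out each uf meristem of a small group gave 2912 to 5423 genes over the later stages, the lowest without EFM replicate 3 (8 fits), 0 to 0 for uf and stage (12 fits) and 2 to 3 at VM (4 fits). Without EFM replicate 3 the CLV3 call ended (1.56, adjusted p = 0.177), without VM replicate 4 that of cathepsin D (1.73, adjusted p = 1). Of the other uf genes named at VM, the RNA-binding protein lost its call in 4 of 4 fits and the BED zinc finger and CONSTANS-interacting genes in 3 of 4. The plate as a covariate could not be fitted for genotype differences, since genotypes share few plates. The labels give no number that pairs meristems of different groups. All 6 wild-type stages were dissected on each of the 5 wild-type days, so there the block compares stages within days, and it gave 0 genes from VM to TM0, 103 from TM0 to TM1, 170 from TM1 to TM2, 142 from LTM to EFM and 1109 for EFM against VM (0, 136, 184, 104 and 954 without it). At these depths and group sizes, simulated 2-fold changes were recovered at 13% for uf at VM and 6% for the interaction of sft and dst.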

Other observations

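The day-by-day comparison and the tests of phase and spike-ins in this part were chosen only after the data were seen.

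The authors' metadata give most meristems a phase beside the stage. At TM2, 16 of 40 sft and 11 of 23 uf meristems were called vegetative, against 1 of 23 in wild type (Fisher's exact test, adjusted p = 0.015 and 0.015), while dst had 1 of 27 (adjusted p = 1). At TM1 the numbers were 20 of 40 in sft, 18 of 35 in dst, 11 of 16 in uf and 16 of 36 in wild type (adjusted p = 0.87, 0.87 and 0.553). How the authors set the phase is not given in the labels, and genotype is confounded with dissection day here too.

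Day means over all stages separated sft and uf from wild type 10-fold on every day with at least 3 meristems in 1 gene each. FUL1 lay at 0.666 to 2.93 CPM in sft and 44.4 to 82.2 in wild type, and a glycine-rich gene (Solyc09g092700) at 0.112 to 0.401 CPM in uf and 4.65 to 22.8 in wild type. The 15 splits of the wild-type days gave 0 such genes. The day means pooled the stages. Of 76 uf meristems 7 were at LTM, 3 at EFM and 18 at TM2E, and of 209 in wild type 44 were at LTM and 40 at EFM. Each wild-type day held 6 stages, so the splits do not test the mix of stages. For the uf gene, stage is therefore not told apart from genotype. No comparison of day means is given for sft dst, which was sampled at VM alone.

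The mean relative log2 value of gene UMIs per spike-in UMI was higher at EFM than at VM by 0.82 in wild type (permutation test, adjusted p = 0.00012). It was higher by 0.9 in dst (exact test, adjusted p = 0.0252) and by 0.59 in sft (permutation test, adjusted p = 0.114). The median gene UMIs per spike-in UMI went from 858 to 1850 in wild type, from 1660 to 3470 in dst and from 2070 to 2950 in sft. In uf, which was not tested, the mean relative log2 value went the other way, from 0.19 at VM (n = 4) to -0.27 at EFM (n = 3). Wells without a meristem held 0.512% to 14.7% of the UMIs of wells with one, with a median of 1.15% over 17 plates.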
